A study of Mus musculus with 6 samples.

How the data were processed

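The data were droplet single-cell RNA sequencing libraries (10x Genomics, v2 chemistry) of the extended PVN, the pituitary and the adrenal gland of C57BL/6 mice. For each tissue, 1 library came from unstressed controls and 1 from mice after chronic social defeat, each from a pool of 5 mice, per the labels. Per the labels' protocols, the mice were perfused with cold saline, the PVN was dissected by hand from a brain slice, brain and pituitary were dissociated with papain and adrenals with collagenase, and the control and stress suspensions of a tissue ran on 1 chip. Strand, cell calling settings and the annotation used for counting were not given in the sources used here.

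The deposited matrices held unnormalised UMI counts per gene and barcode. Per the submitters' processing notes, Cell Ranger 2.1.1 was run on mm10; Scanpy is also named there without a role. The 27998 genes were the same in the 6 libraries, with 65 symbols listed 2 times. The lowest barcode held 2762 and 2549 UMIs in the PVN, 2238 and 2588 in the pituitary and 3536 and 3303 in the adrenal, so the files held only barcodes with many UMIs. Coordinates came from GENCODE vM21 on GRCm38, the assembly that mm10 stands for, matched by gene ID. Genes without coordinates in the report were Nr3c1 (ENSMUSG00000024431, chromosome 18, 39410545 to 39519421, minus strand), Sgk1 (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903, plus strand), Tsc22d3 (ENSMUSG00000031431, chromosome X, 140539528 to 140600659, minus strand), Th (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128, minus strand) and Pnmt (ENSMUSG00000038216, chromosome 11, 98386450 to 98388181, plus strand).

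Barcodes with at least 200 genes and at most 25% mitochondrial UMIs were kept. The limit on mitochondrial UMIs removed 33 and 46 PVN barcodes (0.90% and 1.27%), 45 and 15 pituitary barcodes (0.87% and 0.29%) and 130 and 378 adrenal barcodes (5.58% and 11.9%). The gene minimum was missed by 5 and 7 PVN, 0 and 1 pituitary and 6 and 48 adrenal barcodes. Doublets were scored per library from simulated doublets (2 per cell) among each cell's nearest neighbours, and the highest scores were left out at 0.8% per 1000 cells, which removed 105 and 101 PVN, 213 and 207 pituitary and 39 and 63 adrenal barcodes. The count of doublets was thus set by the rate and not by the scores.

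The kept cells of each tissue were clustered jointly on 2000 variable genes (20 dispersion bins), 30 principal components and 15 neighbours, with the Leiden method at resolution 1 and 5 iterations. Glucocorticoid-responsive, immediate-early, heat-shock, ABC transporter, mitochondrially encoded, ribosomal, haemoglobin and sex-linked genes were left out of the clustering genes, so that cells were not grouped by them. This gave 23 clusters in the PVN, 24 in the pituitary and 15 in the adrenal. A cluster was called X-like from fixed markers, of which at least 3 had to be found in at least 10% of its cells at 2 or more times the level of the lower quartile of clusters. It stayed unnamed where its top 10 genes held more markers of another class. The score that ranks the names averages the fold of the markers against all other cells and against that quartile, and was chosen after an earlier score failed on the dominant classes. Rules that left clusters with markers of 2 unrelated classes unnamed (those of at least 1.5 times the usual depth, or with no marker of the class among their top genes), and rules for dividing and erythroid cells, were set after the clusters had been seen. The clusters so kept out of any class held 49 and 40 (cluster 16) and 6 and 24 cells (cluster 22) in the PVN, and 29 and 3 cells (cluster 22) in the pituitary. In the adrenal they held 216 and 461 (cluster 2, led by Adh1, Nr0b1, Dbp and Hsd3b6), 41 and 59 (cluster 9), 20 and 29 (cluster 12) and 12 and 35 cells (cluster 13).

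UMIs were summed over the cells of a class in each library. A level is the sum scaled to the total UMIs of the class (CPM), with an exact Poisson interval, and a difference is the log2 ratio of stress over control with 0.5 UMI added to each sum and an exact interval for the ratio. Shares have exact Clopper-Pearson intervals. With 1 library per group these intervals describe molecules counted in these pools, not mice. Comparisons of shares of cells with an Abcb1b UMI used cells thinned to 1000 UMIs.

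The 18 gene lists were glucocorticoid-responsive genes (25 listed), corticosteroid receptors and cofactors (8), immediate-early (16), heat-shock (10), unfolded protein response (16), interferon and antigen presentation (14), steroidogenesis (17), cholesterol synthesis (19), ABC transporters (9), catecholamine and granule (13), corticotrope function (12), pituitary hormone (7), hypothalamic neuropeptide (16), myelin (10), nuclear-encoded respiratory chain (16), mitochondrially encoded (13), sex-linked check (6) and proliferation genes (8). Of the listed genes, 1 (Cebpd) was not found in the gene table. A list's median covers genes with at least 10 UMIs over both libraries and is set beside 10000 random lists of the same size drawn within 20 expression bins. The percentile describes these libraries and is not a test. Lists overlap in places, such as Nr4a1 in the immediate-early and corticotrope function lists.

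Named genes followed a fixed rule. In each tissue the 4 classes with the most cells in the smaller library, of those with at least 100 cells in both, were taken, plus the focal class (neuron, corticotrope or zona fasciculata) with at least 30. Genes with at least 50 UMIs and a level in the class no lower than in the whole tissue were ranked by the bound of their exact interval nearest to a ratio of 1, leaving out mitochondrial, ribosomal protein, haemoglobin and nameless genes. The 3 highest and 3 lowest were named, and across tissues the 5 highest and 5 lowest with the same sign in all 3. Named genes that led a cluster of their own class were left out as results: Prok2 and Pmch in neuron-like cells, Klk6 in oligodendrocyte-like cells, Ceacam10 and Ngb in somatotrope-like cells, G0s2 in zona glomerulosa-like cells and Aldh1a7 in zona fasciculata-like cells. This exclusion was not part of the fixed rule and rests on the clusters found. A further gene that the rule named is not reported here. Groups, markers, lists, the rule for named genes and 18 alternatives were fixed before the data were examined.

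Those alternatives were a stricter cell filter (at least 500 genes, at most 10% mitochondrial UMIs), no cell filter, no doublet removal, Leiden resolutions 0.5 and 2, each library clustered alone, and clustering also without the steroidogenesis, cholesterol synthesis, catecholamine, corticotrope function, pituitary hormone and neuropeptide genes. For the ratios they were median-of-ratios and TMM scaling, the mean over cells of counts per 10000, thinning to 1000 UMIs, list minimums of 1 and 50 UMIs, and 5 UMIs added. The ratio in all other kept cells of the tissue was also subtracted, as a check on free RNA, named genes were drawn with no minimum level, and the Abcb1b share was taken with no thinning and at 2000 UMIs. Another 6 were chosen after seeing the data: the zona fasciculata class with adrenal cluster 2 added, the zona glomerulosa class with it added, all cortex clusters together, neuron-like cells without cluster 15, and, for zona fasciculata-like cells, a mitochondrial limit of 10% or none with the gene minimum kept. Counts of cells behind peptide, named and Abcb1b UMIs, Abcb1b by mitochondrial share, and the subtraction of the somatotrope-like profile at the Gh level of each other pituitary class, were also computed only after the data had been seen.

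The statistics were tested on Poisson counts simulated from the libraries' own means, with 200 changed genes in each comparison. The intervals assume the same counting error, so coverage near 95% was built in. UMIs gathered in few cells, as for Gnrh1, were not simulated. For PVN neuron-like cells (12921 genes), the intervals covered 95.6% of true ratios and 93.0% of genes changed 1.5-fold were recovered. For pituitary corticotrope-like cells (6989 genes) these were 95.7% and 80.0%, and for adrenal zona fasciculata-like cells (10093 genes) 95.5% and 86.8%. Genes changed 4-fold were recovered at 100% in each. Of 20 unchanged lists, 20, 19 and 17 lay inside the middle 95% of random lists. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3.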

Results

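The hypothalamic-pituitary-adrenal axis, the hormone cascade through which the brain controls glucocorticoid output, was profiled by droplet single-cell RNA sequencing in C57BL/6 mice. Cells came from the extended paraventricular nucleus of the hypothalamus (PVN), the pituitary and the adrenal gland of 10-week-old mice. The mice were either unstressed controls or had gone through 21 days of chronic social defeat, a model in which a mouse is repeatedly confronted with an aggressive mouse. Each of the 6 groups of tissue and condition held 1 library, made from the pooled tissue of 5 mice. There were therefore no replicates and no test between conditions, and every difference given here compares a pair of pools. The PVN libraries held 3653 cell barcodes with 31110127 UMIs (control) and 3612 barcodes with 29916957 UMIs (stress). The pituitary libraries held 5202 barcodes with 50024887 UMIs and 5103 barcodes with 53244403 UMIs, and the adrenal libraries 2330 barcodes with 29059956 UMIs and 3183 barcodes with 33836656 UMIs. Median depth per barcode was 5820 and 5594 UMIs in the PVN, 9571 and 9926 in the pituitary and 10288 and 9631 in the adrenal. After filters, 3512 and 3459 PVN cells, 4944 and 4880 pituitary cells and 2161 and 2742 adrenal cells were kept. Values are given as control and then stress, levels as UMI counts scaled to the total UMIs of the class (CPM), and differences as the log2 ratio of stress over control. Intervals are exact 95% intervals and cover counting error only.

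The first comparison asked which cell types each library held. Neuron-like cells were 45.2% (43.5 to 46.9) and 45.6% (43.9 to 47.2) of PVN cells. Among PVN glia, oligodendrocyte-like cells were fewer in the stress library, 19.9% (18.5 to 21.2) against 15.5% (14.3 to 16.7), and astrocyte-like cells more, 6.01% (5.24 to 6.85) against 10.8% (9.77 to 11.9). Vascular endothelial-like cells were 5.15% (4.45 to 5.94) and 6.91% (6.09 to 7.81), microglia-like cells 6.15% and 5.03%, and ependymal-like cells, which line the ventricle, 6.49% and 4.94%. Somatotrope-like cells, which make growth hormone, dominated the pituitary at 64.9% (63.6 to 66.2) and 62.6% (61.3 to 64.0). Corticotrope-like cells, the source of ACTH, were 5.60% (4.98 to 6.28) and 5.08% (4.48 to 5.74) of the pituitary, and gonadotrope-like cells 4.29% (3.74 to 4.89) and 3.46% (2.97 to 4.01). Erythroid-like cells (1.25% and 2.30%) and dividing cells (9 and 30 cells, 0.18% and 0.61%) were more frequent in the pituitary stress library.

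In the adrenal, zona glomerulosa-like cells, named for markers of the aldosterone-producing outer cortex, were 33.8% (31.8 to 35.8) and 25.4% (23.7 to 27.0) of kept cells. In cluster 3 of this class, control levels were 394.5 CPM for the corticosterone-forming Cyp11b1 and 22.25 CPM for the aldosterone synthase gene Cyp11b2. Cluster 6 had 373.2 and 17.8 CPM. The marker Dab2 was at 1280 CPM in cluster 3, against 171 CPM in zona fasciculata-like cluster 1. Other cortex cells in the class were thus not excluded. Zona fasciculata-like cells, the glucocorticoid-producing layer, were 28.9% (27.0 to 30.9) and 22.0% (20.5 to 23.6). The order of the zona fasciculata shares depended on the setting: they were 43.3% and 46.2% with no cell filter, 32.9% and 39.8% with each library clustered alone, and 38.9% and 38.8% with cortex cluster 2, which was left unnamed (216 and 461 cells), added. With that cluster added to the zona glomerulosa class instead, as its top genes held more markers of that class, the zona glomerulosa shares were 43.8% and 42.2%. Macrophage-like cells were 14.0% (12.6 to 15.6) and 17.2% (15.8 to 18.6), endothelial-like cells 6.11% (5.14 to 7.20) and 9.99% (8.90 to 11.2), and chromaffin-like cells of the medulla 25 and 42 cells (1.16% and 1.53%). Clusters without a clear identity made up 13.4% and 21.3% of adrenal cells, 1.57% and 1.85% of PVN cells and 0.59% and 0.06% of pituitary cells. Dissection and enzymatic dissociation can set all of these shares.

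**Figure D1:**
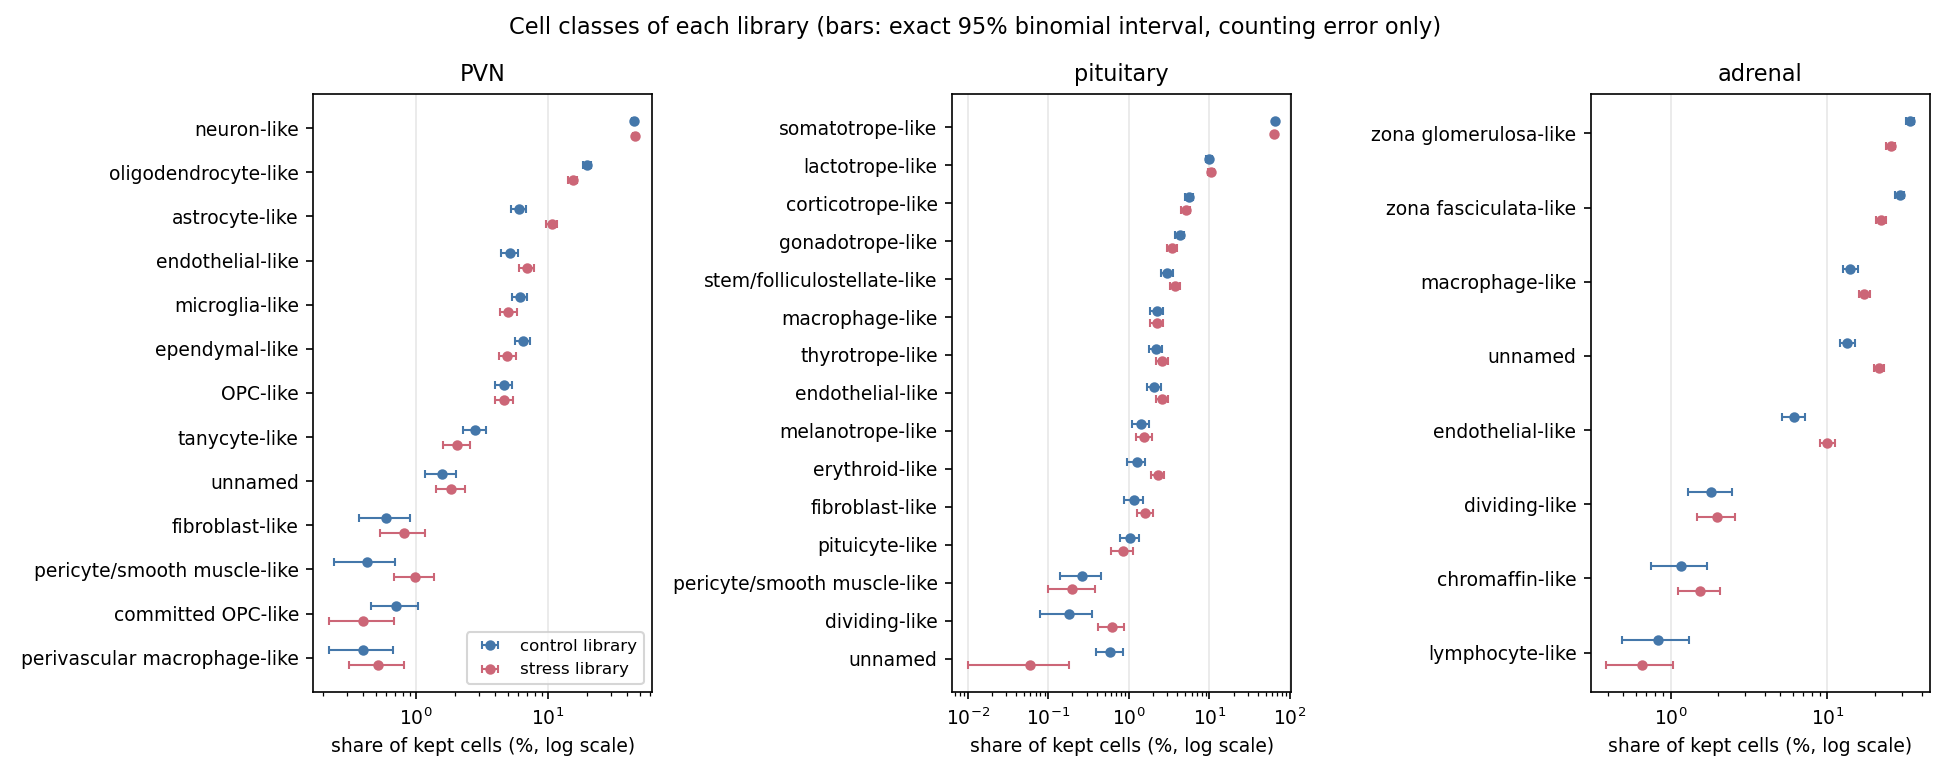
Share of kept cells (%, log scale) in each cell class of the 6 libraries, with exact 95% binomial intervals as bars and OPC for oligodendrocyte precursor cell. Astrocyte-like cells of the PVN (6.01% and 10.8%) lie apart between the control and stress libraries, while neuron-like cells (45.2% and 45.6%) do not, and the gaps of both adrenal cortex classes depend on unnamed cluster 2, with which zona glomerulosa shares are 43.8% and 42.2%, or zona fasciculata shares 38.9% and 38.8%.

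For the PVN, the question was how the neurons that start the axis differed after chronic stress. The hypothalamic neuropeptide genes were lower in neuron-like cells of the stress library (1587 and 1576 cells), with 12 of 16 below control and a median log2 ratio of -0.51. That median lay at percentile 0.0 of 10000 random lists matched on size and expression, and was -0.27 with the ratio in all other PVN cells subtracted. Crh, the releasing hormone that drives corticotropes, was the lowest member at 34.4 and 12.3 CPM, a log2 ratio of -1.48 (-1.71 to -1.26), or -0.76 with the ratio in all other PVN cells subtracted. Oxt, which encodes oxytocin, was at 7454 and 3396 CPM (-1.13, interval -1.15 to -1.12), and Avp, which encodes vasopressin, at 3971 and 2831 CPM (-0.49, interval -0.50 to -0.47). Sst (1210 and 729 CPM, -0.73), Pdyn (-0.94), Npy (-1.08), Cck (-0.67) and Tac1 (-0.69) were also lower, while Vip was the highest member at 13.6 and 32.6 CPM (1.26, interval 1.05 to 1.48). These members other than Crh and Vip, and the members of other lists that are not called highest or lowest, were chosen as examples after their values were seen. Here and for every list, highest and lowest refer to members with at least 50 UMIs over both libraries.

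Few cells carried the peptide transcripts. Cells with 10 or more Crh UMIs numbered 23 and 8, and those with 10 or more Oxt UMIs 43 and 14, whereas Avp passed that level in 117 and 110 cells. Neuron cluster 15, led by Oxt, Sst, Avp, Crh and Cartpt, held 115 and 51 cells, 7.25% and 3.24% of neuron-like cells. Other clusters also took different shares of the class. Cluster 11 (led by Pdyn and Cck) held 171 and 90 cells, and cluster 12 (led by Prok2, Nms and Vipr2) 91 and 164 cells. Cluster 12 held 218 of 254 and 523 of 593 Vip UMIs of the class, and Vip within it was at 0.37 (0.14 to 0.61). The region that these cells came from was not tested. Without cluster 15, the neuropeptide median was -0.32 (5 of 16 higher, percentile 0.0), Oxt was at -2.81 and Crh at -0.26, and Avp reversed to 0.61. Cluster 12 then held most Avp UMIs (16298 and 28151), and Avp within it was at -0.10 (-0.13 to -0.08). Avp was higher in cluster 10 (2.44) and lower in the other 6 neuron clusters, from -0.45 in cluster 2 to -1.70 in cluster 4. Inside cluster 15, the log2 ratio was -2.05 for Crh, -0.23 for Avp and 0.16 for Oxt, and Crh was at -0.22 in cluster 4 and 0.63 in cluster 10. The peptide gene Hcrt, which led cluster 10, was at 5651 and 62.4 CPM there and at 45.9 and 1818 CPM in cluster 4. Ratios within clusters 4 and 10 may thus compare unlike cells. In cluster 19, Crh was at 26 and 0 UMIs, with an upper bound of -2.67 for the log2 ratio. Crh lies on chromosome 3 at 19693401 to 19695396 (minus strand, ENSMUSG00000049796). Avp lies on chromosome 2 at 130580620 to 130582554 (minus strand, ENSMUSG00000037727), next to Oxt at 130576173 to 130577054 (plus strand, ENSMUSG00000027301). All 3 are protein-coding genes in the GRCm38 annotation.

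Immediate-early genes respond fast to neuronal activity, and also to handling and dissociation. In neuron-like cells of the stress library, 14 of 16 were lower (median -0.28, percentile 0.0), and these causes were not separated. Egr2 was the lowest at 23.5 and 12.1 CPM (-0.96, interval -1.20 to -0.72), and Atf3 the highest at 0.12. All 10 heat-shock genes, which encode protein chaperones, were higher (median 0.23, percentile 100), led by Hspb1 at 8.62 and 15.7 CPM (0.86, interval 0.58 to 1.15). Cholesterol synthesis genes were higher for 15 of 19 (median 0.12, percentile 100), led by Cyp51 (0.29). Myelin genes, typical of oligodendrocytes, were lower for 9 of 10 (median -0.26, percentile 0.0). With the ratio in all other PVN cells subtracted, the last 3 medians turned to -0.07 for heat-shock, -0.04 for cholesterol synthesis and 0.02 for myelin. The 13 mitochondrially encoded genes were all higher (0.10, percentile 100), and nuclear-encoded respiratory chain genes lay at 0.03 (12 of 16 higher, percentile 92.2).

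The glucocorticoid-responsive list of the same neurons had a median of -0.04 (7 of 19 higher, percentile 9.1), but of -0.23 in cells thinned to 1000 UMIs. Among members with at least 50 UMIs, Fam107a was the lowest at -0.38 and Mt1 the highest at 0.25. Fkbp5, a co-chaperone long used as a readout of glucocorticoid receptor activity (chromosome 17, 28399094 to 28517527, minus strand, ENSMUSG00000024222), was at 9.80 and 9.51 CPM (-0.04, interval -0.35 to 0.26). Sgk1 was at 18.4 and 16.2 CPM (-0.18, interval -0.41 to 0.04), Tsc22d3 at 0.02 (-0.08 to 0.12), and Nr3c1, the glucocorticoid receptor gene, at 65.8 and 61.6 CPM (-0.09, interval -0.21 to 0.02). A difference in Fkbp5 was thus not detectable at this depth. Lists without a direction outside the middle 95% of random lists were receptors and cofactors (0.02, percentile 59.5), the unfolded protein response (0.04, 86.5), interferon and antigen presentation (-0.12, 8.3), steroidogenesis (0.11, 94.0), ABC transporters (-0.08, 18.0), catecholamine genes (0.01) and corticotrope function genes (0.02).

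**Figure D2:**
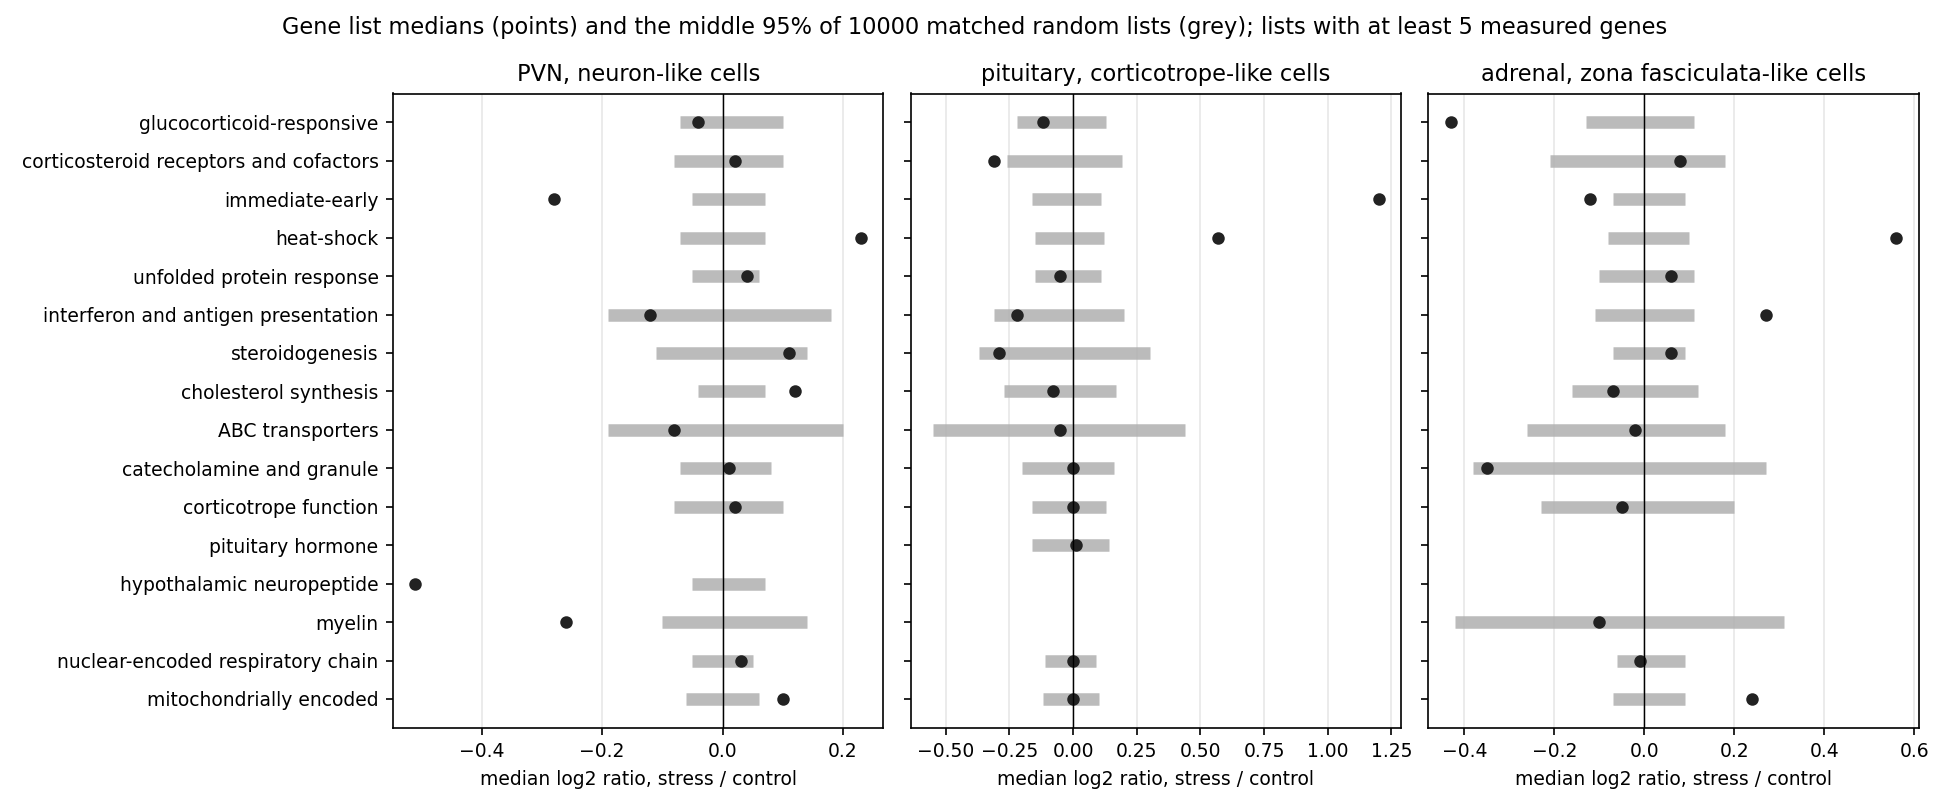
Median log2 ratio (stress over control) of the gene lists with at least 5 measured genes, without the proliferation and sex-linked lists, in PVN neuron-like, pituitary corticotrope-like and adrenal zona fasciculata-like cells; grey bars show the middle 95% of 10000 matched random lists. Of the lists shown, neuropeptide genes stand lowest in neuron-like cells (-0.51), immediate-early genes highest in corticotrope-like cells (1.20), and heat-shock genes highest (0.56) with glucocorticoid-responsive genes lowest (-0.43) in zona fasciculata-like cells.

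The genes named by rule in neuron-like cells came from few cells. Gnrh1, which encodes gonadotropin-releasing hormone, was at 63.9 and 0.99 CPM (-5.97, interval -6.77 to -5.34), with 98.7% of its control UMIs in 5 cells. Qrfp, another neuropeptide gene, was at -3.98 (-5.57 to -2.92) with UMIs in 6 and 5 cells. Nr5a1, a marker of the ventromedial hypothalamus, was higher in the stress library (2.46, interval 1.43 to 3.83; 7 and 32 cells), as was the transcription factor gene Lhx8 (2.03, interval 1.20 to 3.02; 4 and 14 cells). With other PVN cells subtracted, Gnrh1 was at -3.26, Qrfp at -1.14 and Nr5a1 at 1.62.

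Glia and vessels of the PVN showed heat-shock genes higher in the stress library. The median was 0.57 in oligodendrocyte-like cells (10 of 10 higher), 0.73 in oligodendrocyte precursor-like cells (10 of 10), 0.75 in microglia-like cells (10 of 10) and 0.44 in endothelial-like cells (9 of 10). Oligodendrocyte-like cells had more Dnajb1, an Hsp40 chaperone gene (410 and 726 CPM, 0.82, interval 0.73 to 0.92), Swt1 (50.9 and 142 CPM, 1.48, interval 1.23 to 1.74) and Ahsa2 (0.67, interval 0.38 to 0.97), of which Dnajb1 was at 0.43 and Ahsa2 at 0.42 with other PVN cells subtracted. They had less Adamts1, a matrix protease gene (-0.83, interval -1.10 to -0.58), and Aga (-0.87, interval -1.26 to -0.49). Endothelial-like cells had more Icam1, an adhesion molecule for leukocytes (35.9 and 104 CPM, 1.52, interval 1.03 to 2.07), Csf1, a macrophage growth factor (14.9 and 55.1 CPM, 1.86, interval 1.12 to 2.74), and Dnaja1 (0.79, interval 0.65 to 0.94). Ciart, a circadian repressor gene, was lower there (65.6 and 21.6 CPM, -1.59, interval -2.26 to -0.98), as were Prr14 (-1.05, interval -1.63 to -0.50) and Rbmx2 (-1.27, interval -2.19 to -0.43). In astrocyte-like cells, Specc1 (1.12, interval 0.50 to 1.82), Lrtm2 (1.40, interval 0.49 to 2.54) and Fgfrl1 (1.32, interval 0.37 to 2.53) were higher. Fam214a (-1.04, interval -1.53 to -0.56) and Asun (-1.26, interval -2.11 to -0.45) were lower there.

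For the pituitary, the question was whether the corticotropes, which relay the hypothalamic signal, differed after chronic stress. Immediate-early genes were higher for 15 of 16 in corticotrope-like cells of the stress library (277 and 248 cells; median 1.20, percentile 100). Among members with at least 50 UMIs, Socs3, a feedback inhibitor of cytokine signalling, was the highest at 18.1 and 81.6 CPM (2.16, interval 1.62 to 2.78), Fos was at 427 and 1307 CPM (1.61), Jun at 1.72, and Nr4a1 the lowest at 44.0 and 36.6 CPM (-0.26). All 10 heat-shock genes were higher (median 0.57, percentile 100). The inducible Hsp70 gene Hspa1a was at 60.4 and 614 CPM, 10.1-fold higher (8.33 to 12.5), and Dnajb1 at 43.5 and 325 CPM (2.90, interval 2.56 to 3.27), whereas the mitochondrial chaperone gene Hspd1 was at 0.16 (-0.07 to 0.40). With other pituitary cells subtracted, the immediate-early median was 0.18, the heat-shock median 0.23, Hspa1a at 0.75 and Dnajb1 at 1.19.

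The hormone gene Pomc was nearly level between the libraries in corticotrope-like cells. This gene, the precursor of ACTH (chromosome 12, 3954951 to 3960642, plus strand, ENSMUSG00000020660), was at 136400 and 137100 CPM, a log2 ratio of 0.01 (0.00 to 0.02). Its sign depended on the setting, from -0.03 with no cell filter to 0.13 with other pituitary cells subtracted. Of 12 corticotrope function genes, 6 were higher and 6 lower (median 0.00, percentile 60.5). The prohormone convertase gene Pcsk1, which cuts the Pomc product, was the highest at 63.2 and 119 CPM (0.91, interval 0.58 to 1.26), and the orphan receptor gene Nr4a2 the lowest at 58.1 and 38.3 CPM (-0.60, interval -1.07 to -0.15). Pituitary hormone genes had a median of 0.01 (4 of 7 higher), but apart from Pomc these are products of other pituitary cells, such as Gh at 38140 and 47600 CPM. Cartpt was at 50.2 and 154 CPM (1.61, interval 1.27 to 1.98), the median of the 3 neuropeptide genes measured there, all higher, though that median was 0.40 with other pituitary cells subtracted.

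Glucocorticoid-responsive genes of corticotrope-like cells had a median of -0.12 (6 of 18 higher, percentile 16.1). Among members with at least 50 UMIs, Ddit4 was the lowest at 198 and 131 CPM (-0.59) and Cdkn1a the highest at 52.5 and 77.1 CPM (0.55). Fkbp5 was at 112 and 118 CPM (0.07, interval -0.21 to 0.36), though at -0.45 in cells thinned to 1000 UMIs. Nr3c1 was at 157 and 156 CPM (-0.01, interval -0.25 to 0.24), Sgk1 at -0.69 (-1.94 to 0.45) and Tsc22d3 at -0.15. Receptor and cofactor genes were lower for 5 of 7 (median -0.31, percentile 0.8), but the median was -0.04 in thinned cells. Hsp90ab1 was at 1102 and 1445 CPM (0.39), Ncoa1 at -0.56, and Nr3c2, the mineralocorticoid receptor gene, at -1.03 from 23 and 11 UMIs. The medians of the unfolded protein response (-0.05, percentile 31.6), interferon (-0.22, 7.7), steroidogenesis (-0.29, 6.2), cholesterol synthesis (-0.08, 38.4), ABC transporters (-0.05), respiratory chain and mitochondrially encoded genes (0.00 each) stood inside the middle 95% of random lists.

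Named genes of corticotrope-like cells also included Ehd3, an endocytic recycling gene, at 18.6 and 83.9 CPM (2.15, interval 1.62 to 2.76). Ddit4l was lower at 85.2 and 31.0 CPM (-1.45, interval -1.93 to -1.01), and Id2, which encodes an inhibitor of helix-loop-helix factors, at 75.1 and 27.6 CPM (-1.43, interval -1.95 to -0.96). Rgs5, a pericyte marker, was at 28.2 and 0.56 CPM (-5.08, interval -10.98 to -3.10) with UMIs in 5 and 1 cells.

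Immediate-early and heat-shock genes were higher across the whole pituitary. All genes together were shifted by -0.11 in the whole pituitary and by -0.17 in somatotrope-like cells, so the values of both are given relative to these shifts. All 16 immediate-early genes were higher in the whole pituitary, 0.96 above the shift, with Fosb the highest (9.22 and 27.5 CPM) and Ier3 the lowest. The list stood 1.58 above the shift in somatotrope-like cells, and its medians were 0.50 in lactotrope-like, 0.95 in gonadotrope-like, 0.52 in thyrotrope-like, 0.68 in endothelial-like, 0.33 in macrophage-like and 0.16 in stem or folliculostellate-like cells. Each of these lay at percentile 100. Heat-shock genes were 0.67 above the shift in the whole pituitary, with Hspa1a at 51.8 and 321 CPM. The 8 proliferation genes were all higher, by a median of 0.92 relative to the shift, led by Ube2c at 1.31 and 3.70 CPM. Mitochondrially encoded genes were lower for 12 of 13, by -0.08 relative to the shift.

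Among pituitary hormones, Lhb, the beta subunit of luteinizing hormone, was the lowest in the whole tissue at 3072 and 1620 CPM, and Tshb, the beta subunit of thyrotropin, the highest at 512 and 713 CPM. Gh was at 426600 and 453800 CPM. Gonadotrope-like cells were 4.29% and 3.46% of the pituitary, and thyrotrope-like cells 2.16% (1.78 to 2.61) and 2.58% (2.16 to 3.07), with overlapping intervals in both classes. In gonadotrope-like cells, Nr4a1, an immediate-early nuclear receptor gene, was at 11.3 and 64.4 CPM (2.49, interval 1.91 to 3.16), Npas4, an activity-dependent factor, at 2.61 (1.67 to 3.81) and Dnajb1 at 43.5 and 192 CPM (2.14, interval 1.83 to 2.46). Begain (-1.59, interval -2.63 to -0.73), Limd2 (-1.11, interval -1.62 to -0.63) and Nr0b2 (-1.26, interval -1.98 to -0.62) were lower there. In lactotrope-like cells, which make prolactin, Hspb1 (83.7 and 174 CPM, 1.05, interval 0.87 to 1.25), Hsp90aa1 (392 and 682 CPM, 0.80, interval 0.71 to 0.89) and Tubb6 (1.06, interval 0.71 to 1.42) were higher. Dnaic2 (-1.61, interval -2.32 to -0.97), Akr1c14 (-1.38, interval -2.03 to -0.79) and Hif1an (-1.49, interval -2.27 to -0.79) were lower. With other pituitary cells subtracted, Hspb1 turned to -0.06 and Akr1c14 to 0.74, and Hsp90aa1 was at 0.22, Tubb6 at 0.56, and Dnajb1 and Npas4 of gonadotrope-like cells at 0.36 and 1.72. Relative to the shift of somatotrope-like cells, Ly6f (1.94) and Pla2g2e (1.75) were higher and Cd79a, a B-cell gene (4.20 and 0.98 CPM, -1.91), and Wfikkn2 (-1.26) lower. With other cells subtracted, from ratios not corrected for this shift, Pla2g2e was at 0.64, Cd79a at -1.28 and Wfikkn2 at -0.24. Clusters took different shares of the somatotrope-like cells in the libraries, with 943 and 553 cells in cluster 1 and 514 and 940 cells in cluster 2.

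**Figure D3:**
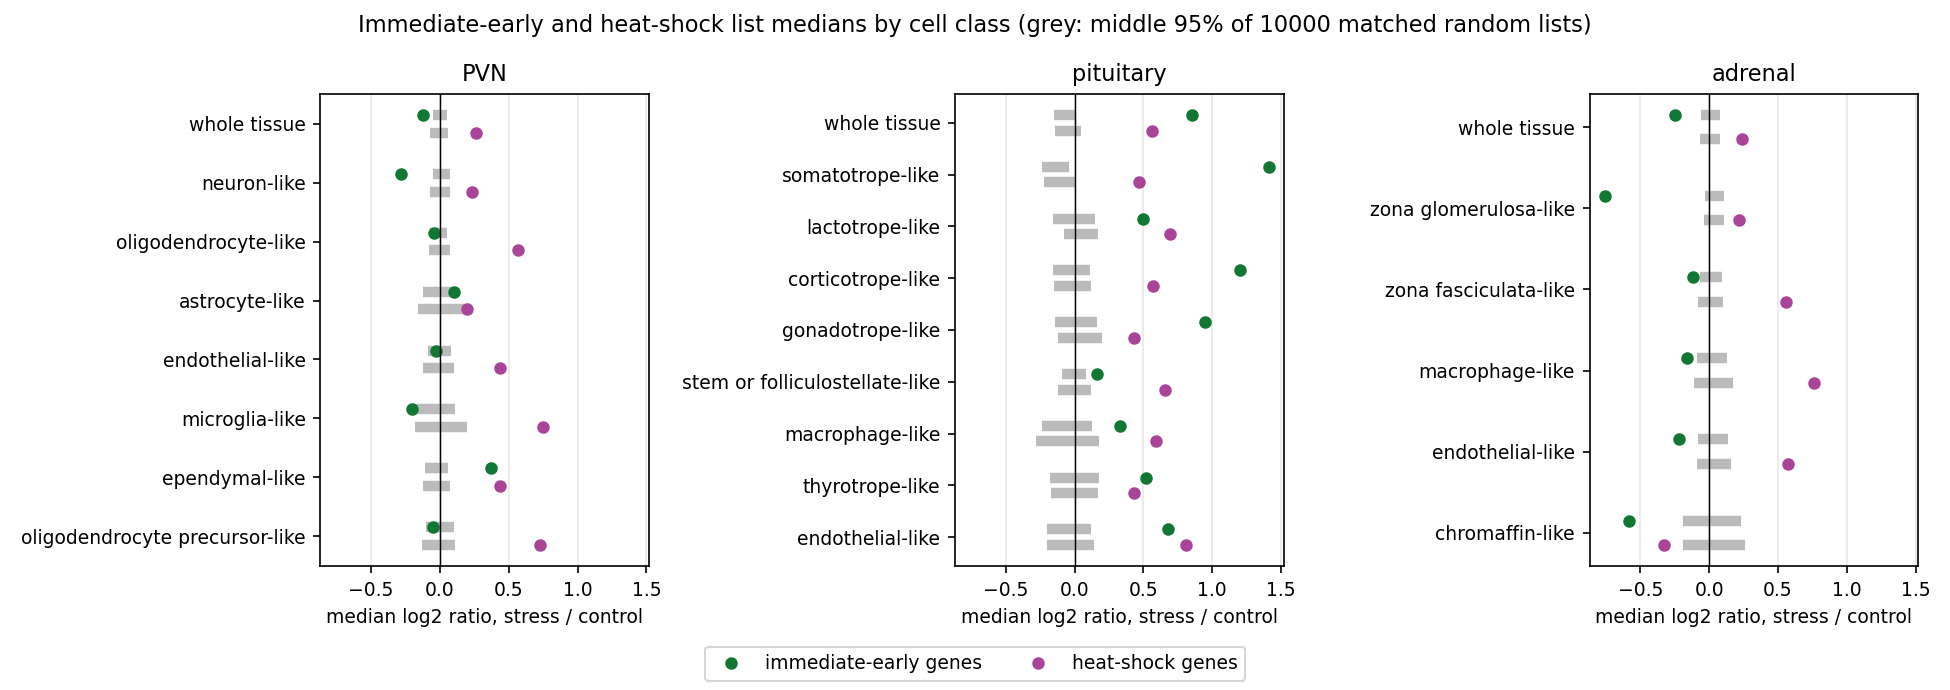
Median log2 ratio (stress over control) of immediate-early and heat-shock genes in the whole tissue and each cell class; grey bars show the middle 95% of 10000 matched random lists. Immediate-early medians lie above 0 in every pituitary class shown and below 0 in every adrenal class shown, and heat-shock medians are positive in every class shown except chromaffin-like cells (-0.33).

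For the adrenal, the question was how the glucocorticoid-producing cortex differed, and the series title points to ABCB1, a drug efflux pump that also transports steroids. Glucocorticoid-responsive genes were lower for 18 of 22 in zona fasciculata-like cells of the stress library (625 and 604 cells; median -0.43, percentile 0.0). Arl4d was the lowest at 9.83 and 3.63 CPM (-1.42, interval -2.11 to -0.81), Cdkn1a, a cell cycle inhibitor gene, was at 50.8 and 22.7 CPM (-1.16), Nfkbia, which restrains NF-kB, at 154 and 82.4 CPM (-0.90), and Xdh the highest at 0.39 (0.05 to 0.73). Fkbp5 was at 46.7 and 31.9 CPM (-0.55, interval -0.78 to -0.32). Tsc22d3 was at 31.1 and 25.8 CPM (-0.27, interval -0.54 to 0.00), Sgk1 at 29.4 and 34.7 CPM (0.24, interval -0.01 to 0.49) and Nr3c1 at 10.7 and 8.43 CPM (-0.35, interval -0.83 to 0.12).

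Steroidogenesis genes were mixed in zona fasciculata-like cells, with 10 of 17 higher and a median of 0.06 (percentile 85.6). Fdx1, the ferredoxin that feeds electrons to the steroid hydroxylases, was the highest at 2325 and 3405 CPM (0.55, interval 0.52 to 0.58), and Akr1b7 the lowest at 5054 and 3194 CPM (-0.66, interval -0.68 to -0.64). Star, which moves cholesterol into mitochondria (chromosome 8, 25806555 to 25815982, plus strand, ENSMUSG00000031574), was at 2235 and 2740 CPM (0.29, interval 0.27 to 0.32). Cyp11b1, the corticosterone-forming 11-beta-hydroxylase (chromosome 15, 74834125 to 74841643, minus strand, ENSMUSG00000075604), was at 2381 and 2478 CPM (0.06, interval 0.03 to 0.09). Cholesterol synthesis genes had a median of -0.07 (9 of 19 higher, percentile 26.1), and -0.34 under the stricter cell filter, from Pmvk at 29.5 and 19.6 CPM (-0.59) to Mvd at 3.28 and 5.83 CPM (0.82). Heat-shock genes were higher for 9 of 10 (median 0.56, percentile 100), led by Hsph1 at 101 and 210 CPM (1.06, interval 0.94 to 1.18), but their median was 0.10 with each library clustered alone, 0.14 with no cell filter and 0.32 with other adrenal cells subtracted. Immediate-early genes were lower for 12 of 16 (median -0.12, percentile 0.3), with Nr4a1, an ACTH-induced gene in the cortex, at 610 and 279 CPM (-1.13, interval -1.20 to -1.06).

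Interferon and antigen presentation genes were higher for 13 of 14 in zona fasciculata-like cells (median 0.27, percentile 100), led by Ifit3 (1.12, interval 0.39 to 1.91), but at -0.05 with other adrenal cells subtracted and -0.03 with each library clustered alone. Mitochondrially encoded genes were higher for 10 of 13 (0.24, percentile 100), and at -0.03 with a limit of 10% mitochondrial UMIs. Barcodes over 25% mitochondrial UMIs were 5.58% and 11.9% of the adrenal libraries, and cluster 8, with a median of 17.2%, was 8.96% and 14.4% of the class. ABC transporters (-0.02, percentile 51.2), receptors and cofactors (0.08, 83.1), the unfolded protein response (0.06, 80.3), catecholamine genes (-0.35, 3.5), corticotrope function genes (-0.05) and respiratory chain genes (-0.01) stood inside the middle 95%. Among the named genes, Crem, a cAMP-responsive modulator, was at 114 and 269 CPM (1.23, interval 1.13 to 1.34), the small heat-shock gene Hspb8 at 9.72 and 34.4 CPM (1.82, interval 1.47 to 2.19) and Abtb2 at 1.48 (1.00 to 2.0). Gpx3 was lower (-2.61, interval -3.20 to -2.10), with 62.0% of its control UMIs in 5 cells. Ly6k was at 58.6 and 3.89 CPM (-3.89, interval -4.50 to -3.38), with UMIs in 15 and 3 cells. With other adrenal cells subtracted, Hspb8 was at 0.76 and Ly6k at -1.19.

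Abcb1b, the rodent ABCB1 gene expressed in the adrenal (chromosome 5, 8798147 to 8866315, plus strand, ENSMUSG00000028970), was at 389 and 570 CPM in zona fasciculata-like cells, 1.47-fold higher in the stress library (1.40 to 1.53; log2 0.55, interval 0.49 to 0.62). Its neighbour and paralog Abcb1a (8660077 to 8748575, plus strand, ENSMUSG00000040584) was at 6.21 and 3.24 CPM (-0.92, interval -1.68 to -0.23). How the counting divided reads between these paralogs was not tested, so the split between them is uncertain. In cells thinned to 1000 UMIs, 15.7% (12.9 to 18.8; 98 of 625) and 21.4% (18.2 to 24.9; 129 of 604) held an Abcb1b UMI, at median depths before thinning of 12704 and 11755 UMIs. For comparison, the share was 2.47% (1.47 to 3.87) and 2.30% (1.32 to 3.71) in zona glomerulosa-like cells, at median depths of 11369 and 11470 UMIs, and 2.27% (0.47 to 6.50) and 2.92% (1.27 to 5.67) in endothelial-like cells, at 4880 and 4273 UMIs. In chromaffin-like cells, the planned background, it was 4.0% (0.1 to 20.35) and 4.76% (0.58 to 16.16), from 1 of 25 and 2 of 42 cells. Macrophage-like cells were at 5.61% (3.3 to 8.83) and 6.37% (4.34 to 8.97). Unthinned shares were 57.9% and 57.5% in zona fasciculata-like, 26.0% and 26.3% in zona glomerulosa-like and 6.82% and 15.0% in endothelial-like cells, and thinning left out 0 cells. At 2000 UMIs the shares were, in the same order, 22.7% and 28.2%, 4.38% and 4.89%, and 2.27% (0.47 to 6.50) and 9.12% (5.99 to 13.2). Abcb1b was at 24.7 and 25 CPM in zona glomerulosa-like cells (0.02), at -0.02 (-0.37 to 0.35) in macrophage-like cells and at 12.5 and 33.1 CPM in endothelial-like cells (1.34, interval 0.35 to 2.62). In chromaffin-like cells it was lower, at 234 and 27.4 CPM (-3.04, interval -4.25 to -2.09; 47 and 10 UMIs), with all control UMIs in 1 cell.

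Most Abcb1b transcripts came from a small set of cells. Cells with 10 or more Abcb1b UMIs numbered 65 and 92 among zona fasciculata-like cells and held 79.4% and 87.1% of the class's Abcb1b UMIs. The level was highest in cluster 8, led by Aldh1a1, Mgst2 and Abcb1b, at 5385 and 4656 CPM (-0.21, interval -0.28 to -0.14). This cluster held 56 and 87 cells, 8.96% (6.84 to 11.5) and 14.4% (11.7 to 17.5) of the class, but 2.59% (1.96 to 3.35) and 3.17% (2.55 to 3.90) of kept cells, where the intervals overlap. The mitochondrial limit also left out 21 and 158 barcodes with 10 or more Abcb1b UMIs. In cluster 1, Abcb1b was at 131 and 132 CPM (0.02, interval -0.14 to 0.18), and in cluster 7, led by Mt2, Ier3 and Cyr61, at 41.8 and 54.3 CPM (0.37, interval 0.01 to 0.74). Outside the class, it was higher in unnamed cortex cluster 2, at 16.8 and 31.05 CPM (0.87, interval 0.39 to 1.41). In clusters 3, 4 and 6 the intervals included 0. Aldh1a1, which led cluster 8, was at 1538 and 318 CPM in that cluster (-2.27) and at -2.88 in cluster 1. The direction depended on the mitochondrial filter, and cluster 8 had a median of 17.2% mitochondrial UMIs. With the other filters kept, the class ratio was -1.53 with at most 10% mitochondrial UMIs and 1.07 with no limit. Barcodes with 10 or more Abcb1b UMIs numbered 33 and 8 at up to 10% mitochondrial UMIs and 38 and 91 from 10 to 25%. The class ratio was 0.07 with each library clustered alone.

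**Figure D4:**
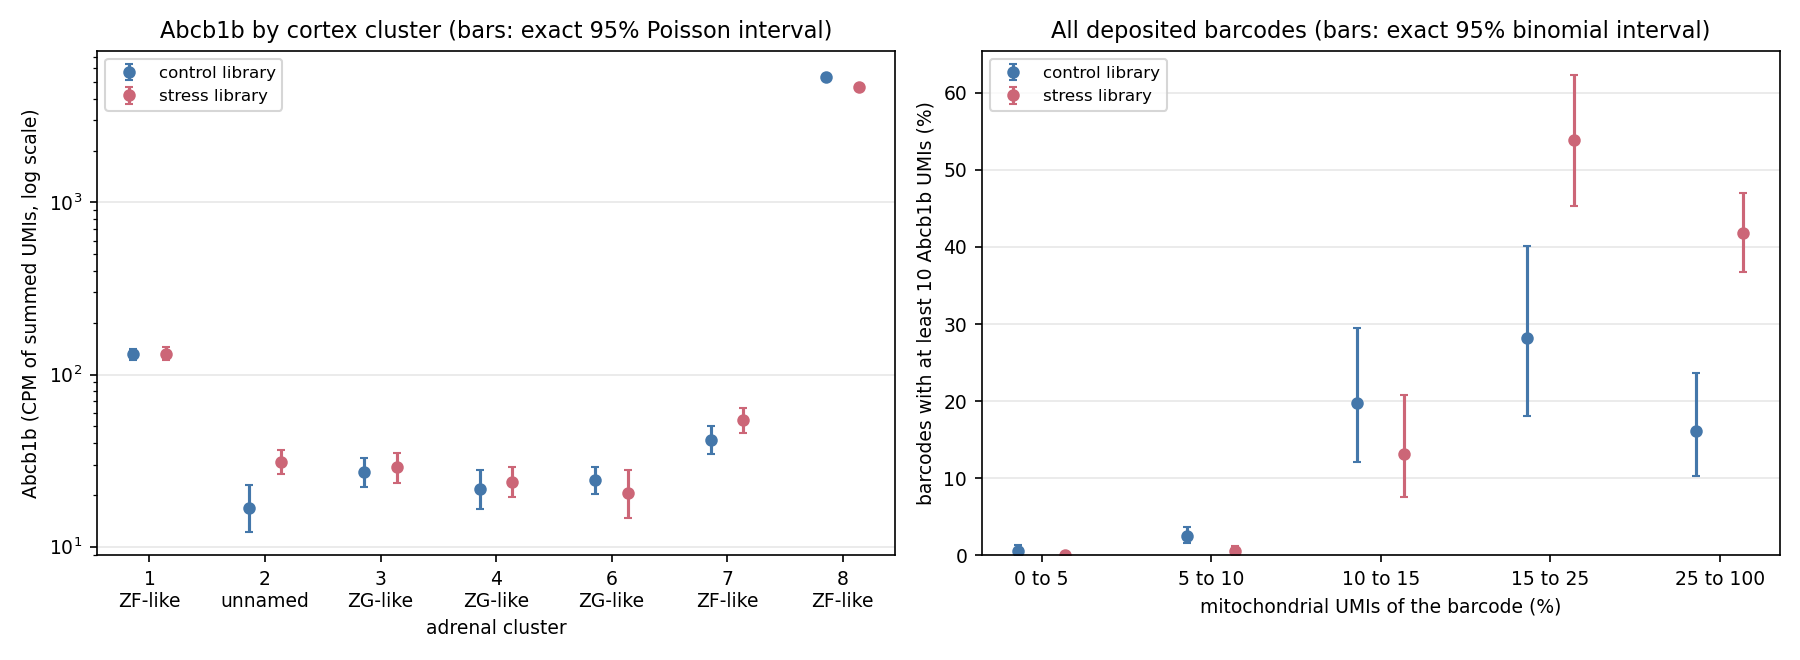
Abcb1b level (CPM, log scale) in each adrenal cortex cluster (ZF, zona fasciculata; ZG, zona glomerulosa), with exact 95% Poisson intervals, and share of all adrenal barcodes with at least 10 Abcb1b UMIs (%) by the barcode's percentage of mitochondrial UMIs, with exact 95% binomial intervals. Cluster 8 stands far above the other clusters at 5385 and 4656 CPM. The share is higher in the stress library above 15% mitochondrial UMIs (53.9% against 28.2% from 15 to 25%). It is lower in the stress library below 15%, at 0.57% against 2.51% from 5 to 10%, and at 13.2% against 19.8% from 10 to 15%, where the intervals overlap.

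Zona glomerulosa-like cells (730 and 695) had lower immediate-early genes in the stress library for 15 of 16 (median -0.76, percentile 0.0) and lower glucocorticoid-responsive genes for 14 of 20 (-0.58, percentile 0.0). Cholesterol synthesis genes were higher for 15 of 19 (0.15, percentile 99.7), and Star was at 1281 and 1571 CPM (0.29). Clusters took different shares of this class in the libraries: cluster 6, led by Gem, Rgs4 and G0s2, held 270 and 132 cells, and cluster 4, led by the aldosterone synthase gene Cyp11b2, 168 and 288 cells. The clock-controlled factor gene Dbp was at 87.6 and 210 CPM (1.26, interval 1.15 to 1.37), but it also led the unnamed cortex cluster and turned to -0.66 with other adrenal cells subtracted. Chst1 (2.06, interval 1.12 to 3.21) and Ndrg4 (1.55, interval 1.04 to 2.09) were higher. Rab21 (-1.14, interval -1.43 to -0.85) and Ly6k (-4.23, interval -4.88 to -3.69; UMIs in 16 and 3 cells) were lower. With other adrenal cells subtracted, these were at 0.83 (Chst1), 0.60 (Ndrg4), -0.44 (Rab21) and -1.61 (Ly6k).

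Chromaffin-like cells, which make adrenaline and noradrenaline, had higher catecholamine and granule genes for 9 of 13 (median 0.25, percentile 97.6), though at -0.23 with other adrenal cells subtracted. In the same cells steroidogenesis genes, typical of the cortex, were lower for 15 of 16 (-1.05). The cluster of chromaffin-like cells scored 5.34 for chromaffin and 4.87 for Schwann or sustentacular markers, so a mixture was not excluded. Th, the rate-limiting enzyme of catecholamine synthesis, was at 1151 and 1502 CPM (0.38, interval 0.16 to 0.61), and, among members with at least 50 UMIs, Pcsk1n was the highest at 1660 and 2510 CPM (0.60, interval 0.41 to 0.78) and Dbh the lowest at 3444 and 2691 CPM (-0.36, interval -0.50 to -0.21). Pnmt, which forms adrenaline, was at 4.98 and 27.4 CPM, with an interval from -0.35 to 7.90 that leaves its direction open at this depth. In macrophage-like cells, Txnip (65.1 and 137 CPM, 1.07, interval 0.78 to 1.36), Hist1h1e (1.76, interval 0.91 to 2.83) and Tnfaip8l2 (41.0 and 99.1 CPM, 1.27, interval 0.92 to 1.64) were higher. Slc7a11, the cystine transporter gene (158 and 58.2 CPM, -1.44, interval -1.71 to -1.17), Clec4d (-1.83, interval -2.38 to -1.32) and Rgl1 (-1.75, interval -2.42 to -1.12) were lower. With other cells subtracted, Tnfaip8l2 turned to -1.29 and Clec4d to 0.47, and Txnip was at 0.59 and Slc7a11 at -0.66. Endothelial-like cells had more Sox18, an endothelial transcription factor (107 and 368 CPM, 1.77, interval 1.43 to 2.15), Ifit2 (1.46, interval 0.64 to 2.49) and Tmsb10 (0.76, interval 0.58 to 0.95). Rnd3 (95.9 and 25 CPM, -1.93, interval -2.58 to -1.33), Ier5l (-1.98, interval -2.93 to -1.13) and Ybx3 (-1.39, interval -1.92 to -0.88) were lower there. With other cells subtracted, Sox18 was at 0.63, Ifit2 at 0.34, Tmsb10 at 0.35 and Ier5l at -1.06.

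Across the tissues, the last comparison asked which genes and lists differed alike in all parts of the axis. Heat-shock genes were higher for 10 of 10 in the whole PVN (0.26), the whole pituitary (0.67 above its shift) and the whole adrenal (0.24), each at percentile 100. Immediate-early genes were lower for 16 of 16 in the PVN (-0.12, percentile 0.0), higher for 16 of 16 in the pituitary and lower for 13 of 16 in the adrenal (-0.25, percentile 0.0). The difference between tissues was not tested. Glucocorticoid-responsive genes had medians of 0.00 in the PVN (percentile 50.7), 0.04 in the pituitary (99.9, or 0.15 relative to the shift) and 0.01 in the adrenal (44.7). Serpinh1, the collagen chaperone, was higher in all tissues (0.48 in the PVN, 0.64 relative to the shift in the pituitary, 0.31 in the adrenal), as were Angptl4, a lipoprotein lipase inhibitor gene (0.57, 1.03 and 0.61), the enkephalin precursor Penk (0.36, 0.68 and 0.83), and the endothelial genes Ly6a (0.32, 0.54 and 0.79) and Ctla2a (0.46, 0.52 and 0.73). Endothelial-like cells were also 5.15% and 6.91% of the PVN and 6.11% and 9.99% of the adrenal, and 2.08% (1.70 to 2.52) and 2.58% (2.16 to 3.07) of the pituitary, where the intervals overlap. Cirbp, the cold-inducible RNA-binding protein, was lower in all (357 and 297 CPM in the PVN, 161 and 111 in the pituitary, 116 and 94.7 in the adrenal), as were the microglial gene Siglech (-0.36, -0.78 and -1.41), Enpp2 (-0.22, -0.21 and -0.55), Prox1 (-0.30, -0.27 and -0.26) and Nudt16 (-0.27, -0.24 and -0.35). Prox1 in the pituitary turned to 0.19 in thinned cells.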

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

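Among the tests given in this part, the test of free RNA from somatotrope-like cells, the one without neuron cluster 15, those that changed the mitochondrial limit alone and both tests on the number of cells in the Abcb1b-high cluster were chosen only after the result was seen, and so were the limits that brought these results up.

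Immediate-early genes went opposite ways in the tissues, with a median log2 ratio of 0.85 in the whole pituitary (0.96 above the shift of all genes), -0.12 in the whole PVN and -0.25 in the whole adrenal; the difference between tissues was not tested. Free RNA from somatotrope-like cells was argued against as the cause in other classes: with the somatotrope-like profile subtracted at each class's Gh level, the median was still 0.27 in macrophage-like cells, which held the most Gh (18.2% and 21.2% of the somatotrope-like level), and 0.16 to 1.20 over 7 classes, each above matched random lists. In cells thinned to 1000 UMIs the pituitary median was 0.83. Levels were already scaled to total UMIs, so thinning mainly gives cells equal weight and does not decide whether depth played a part. Handling or dissociation that reached every cell class of the pituitary pool stays a candidate explanation, as the medians in the 4 smaller classes all lay above matched random lists, at 0.16 in stem or folliculostellate-like, 0.33 in macrophage-like, 0.52 in thyrotrope-like and 0.68 in endothelial-like cells. A response to the chronic stress itself would give the same values and stays open, untested, because each condition was 1 pool.

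The lower neuropeptide genes of PVN neuron-like cells could come from fewer cells of peptide-rich cluster 15. Without that cluster the list median was still -0.32, at percentile 0.0 of matched random lists. The lower median was thus not limited to cells of that cluster. Leaving it out removes neither free RNA from its cells nor other peptide-rich cells, so the test does not decide the question. Oxt was at 195.5 and 96.4 CPM in cluster 0 and at 13410 and 1375 CPM in cluster 10. Hcrt, which led cluster 10, was at 5651 and 62.4 CPM there, so the cells of that cluster may differ in kind between the libraries. Single genes moved more without cluster 15. Crh went from -1.48 to -0.26, though it was also lower within that cluster (-2.05), so cell number and level are not separated for it. Avp went from -0.49 to 0.61, with 91 and 164 cells in Avp-rich cluster 12, led by Prok2, Nms and Vipr2. Oxt went further down to -2.81. The median was -0.37 in thinned cells, but levels were already scaled to total UMIs, so this does not decide whether depth played a part. A slightly different dissected region stays open, as do chronic stress, free RNA from peptide-rich cells and the small number of such cells, none of which was tested.

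Abcb1b was higher in zona fasciculata-like cells of the stress library (0.55), and the limit on mitochondrial UMIs was argued against in 1 direction only: removing it alone gave 1.07 and removing the whole cell filter 0.90, yet a limit of 10% alone gave -1.53, with 33 and 8 barcodes of 10 or more Abcb1b UMIs below that limit and 38 and 91 from 10 to 25%. Free RNA was argued against, as 0.43 remained with the ratio in other cells subtracted. The share of the class in the Abcb1b-high cluster (8.96% and 14.4%, but 2.59% and 3.17% of kept cells, with overlapping intervals) may account for the difference: within that cluster the ratio was -0.21, with each cluster held at its control share of UMIs it was -0.14, and the other clusters stood at 0.02 and 0.37 (interval 0.01 to 0.74). The last value was above what the first of these tests allowed, though at a low level of 41.8 and 54.3 CPM. Both tests take cluster 8 as the same kind of cells in both libraries, although its leading gene Aldh1a1 was at 1538 and 318 CPM there. Abcb1b was also higher in unnamed cortex cluster 2, outside the class (0.87, interval 0.39 to 1.41). Whether stress, damage to mitochondria-rich cells during dissociation or the part of the gland sampled set the share of the Abcb1b-high cluster was not tested.

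Nuclear-encoded respiratory chain genes had a median of 0.05 in the whole PVN and -0.06 in the whole adrenal, outside the middle 95% of matched random lists on opposite sides, and the difference was not tested. Mitochondrially encoded genes had a median of 0.06 in the whole PVN and -0.19 in the whole pituitary (-0.08 relative to the shift of all genes), again on opposite sides and not tested. Among adrenal barcodes over 25% mitochondrial UMIs, which the main filter left out, 41.8% of the stress library (158 of 378) and 16.2% of the control library (21 of 130) held at least 10 Abcb1b UMIs. Unnamed cluster 22 of the PVN, led by Ttr and haemoglobin genes, held 0.69% of stress and 0.17% of control cells. Unnamed cluster 2 of the adrenal held 16.8% of stress and 10.0% of control cells.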

How the results depend on the processing

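The settings that added adrenal cluster 2 to the zona fasciculata or the zona glomerulosa class, joined all cortex clusters, changed the mitochondrial limit alone or left out neuron cluster 15 were tests chosen only after the results were seen; the others were planned. No paired analysis was possible because each group holds 1 library. The 25 values that answer a comparison were recomputed 334 times: 262 stayed within the interval of the reported value, 69 moved beyond it, and 3 took the other sign although that interval lay off 0. Of 2561 recomputed values for 224 single genes, other lists and shares, these were 2280, 266 and 15. Values whose interval included 0 count as moved even where their sign differs. With a list minimum of 50 UMIs all 59 values stayed, with 5 UMIs added 167 of 169, with TMM 163 of 169 and with median-of-ratios scaling 161 of 169, while thinning kept 114 of 165 and subtracting other cells 70 of 133. Drawing named genes with no minimum level kept 3 of 12 values and moved 9, so the choice of named genes depended on that minimum. Where a cause is not named, the cause was not tested. Depth limits genes of low level, as for Pnmt in chromaffin-like cells (1 and 10 UMIs), where intervals are wide.

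Under the stricter cell filter the Abcb1b ratio in zona fasciculata-like cells reversed to -1.53. A mitochondrial limit of 10% alone kept the same number of adrenal cells (2005 and 2498) and gave the same value, and 33 and 8 barcodes with 10 or more Abcb1b UMIs lay below it. The share of such cells with an Abcb1b UMI was then 10.1% in the control and 7.62% in the stress library. The same filter gave a cholesterol synthesis median of -0.34 in zona fasciculata-like cells, Pomc at -0.01, Avp at -0.43, neuron-like shares of 40.9% and 40.5%, a corticotrope-like share of 4.43% in the stress library, and zona fasciculata-like shares of 26.7% and 25.7%; the zona fasciculata values were the same with the limit of 10% alone. With no mitochondrial limit but the gene minimum kept, Abcb1b was at 1.07, the class shares at 36.0% and 35.4%, and the shares with an Abcb1b UMI at 18.8% and 30.3%. With no cell filter Abcb1b was at 0.90, Pomc at -0.03 and the zona fasciculata-like shares at 43.3% and 46.2%. With no doublet removal Pomc was at 0.03 and Avp at -0.54.

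At Leiden resolution 0.5 Abcb1b was at 0.26, the zona fasciculata-like shares at 40.2% and 39.6%, and the shares with an Abcb1b UMI at 11.8% and 13.2%. At resolution 2 these were 0.46, 34.7% and 29.4%, and 16.9% in the stress library. With each library clustered alone Abcb1b was at 0.07, the zona fasciculata-like shares were 32.9% and 39.8%, the stress share with an Abcb1b UMI was 13.1%, and the interferon median of zona fasciculata-like cells reversed to -0.03. Clustering also without the function lists gave 0.48 for Abcb1b, 34.6% and 29.2% zona fasciculata-like cells, and 17.0% with an Abcb1b UMI in the stress library. With cluster 2 added Abcb1b was at 0.21, the class shares at 38.9% and 38.8%, and the Abcb1b shares at 12.1% and 13.3%; with all cortex clusters together Abcb1b was at 0.35. Added to the zona glomerulosa class, cluster 2 gave shares of 43.8% and 42.2%. The Abcb1b share was 57.9% and 57.5% with no thinning and 22.7% and 28.2% at 2000 UMIs, as deeper cells show more genes.

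The mean over cells gave 0.35 for Abcb1b, 0.11 for Pomc and -0.30 for Avp. TMM gave 0.05 for Pomc and median-of-ratios scaling -0.51 for Avp. In cells thinned to 1000 UMIs Crh was at -2.21, Avp at -0.30, Pomc at 0.11, Fkbp5 of corticotrope-like cells at -0.45, the glucocorticoid-responsive median of PVN neuron-like cells at -0.23, and Prox1 of the whole pituitary reversed to 0.19. Without neuron cluster 15 Crh was at -0.26 and Avp reversed to 0.61.

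With the ratio in other cells of the tissue subtracted, as a check on free RNA, Abcb1b was at 0.43, Pomc at 0.13, Crh at -0.76, Avp at -0.39 and the catecholamine median of chromaffin-like cells at -0.23. The subtracted ratios were not corrected for the shift of all genes, which was -0.11 in the whole pituitary and -0.03 in corticotrope-like cells. The ratio reversed for Prok2 (-2.14) in neuron-like cells, Klk6 (0.40) in oligodendrocyte-like cells, Ceacam10 (-0.52) in somatotrope-like cells, Hspb1 (-0.06) and Akr1c14 (0.74) in lactotrope-like cells, Dbp (-0.66) in zona glomerulosa-like cells, and Tnfaip8l2 (-1.29) and Clec4d (0.47) in adrenal macrophage-like cells. Medians reversed in neuron-like cells for heat-shock (-0.07), cholesterol synthesis (-0.04) and myelin genes (0.02), and in zona fasciculata-like cells for interferon (-0.05) and proliferation genes (-0.29). A reversal here means that the ratio in other cells lay further from 0 on the same side, not that the class did not differ. UMIs of a gene in other cells can be free RNA from the class itself, so the subtraction can also remove the class's own difference. Klk6, which leads an oligodendrocyte-like cluster, was at -1.16 in that class and -1.56 in other cells.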

Other observations

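The values in this part were looked up only after the main results had been seen, apart from the list medians, and no tests were made on them.

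Proliferation genes, markers of dividing cells, were higher for 8 of 8 in the whole adrenal of the stress library (median 1.41, percentile 100 of matched random lists). They were led by Ube2c at 7.80 and 29.8 CPM (1.93, interval 1.72 to 2.15). Dividing cells were 1.80% and 1.97% of its kept cells. Unnamed cluster 13, which also held Mki67, Top2a and Ube2c, was 0.56% (0.29 to 0.97) and 1.28% (0.89 to 1.77). In zona fasciculata-like cells 4 of them could be measured (1.26, 4 of 4 higher), but the median was -0.29 with other adrenal cells subtracted. Catecholamine and granule genes went different ways in classes that are not chromaffin-like, with medians of 1.29 in zona glomerulosa-like cells (8 of 9 higher), 1.73 in macrophage-like cells (7 of 7) and 0.95 in endothelial-like cells (4 of 5), but -0.35 in zona fasciculata-like cells (3 of 9, percentile 3.5). They were at 0.72 in the whole adrenal (13 of 13), where chromaffin-like cells numbered 25 and 42, and free RNA from these was not excluded. Interferon and antigen presentation genes were higher for 13 of 14 in the whole adrenal (0.46, percentile 100) and for 10 of 14 in its endothelial-like cells (0.31, percentile 100). In chromaffin-like cells heat-shock genes were lower in the stress library (-0.33, 2 of 10 higher), and steroidogenesis genes were lower for 15 of 16 (-1.05).

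Microglia-like cells of the PVN stress library held more myelin transcripts, with 9 of 9 genes higher (median 1.74, percentile 100), whereas astrocyte-like cells held fewer (-0.73, 0 of 8 higher) and the whole PVN was at -0.31 (0 of 10 higher). Unfolded protein response genes were higher in astrocyte-like cells (0.34, 12 of 14) and microglia-like cells (0.34, 11 of 14). In ependymal-like cells immediate-early genes were higher (0.37, 15 of 16, percentile 100), against a median of -0.28 in neuron-like cells. In pituitary endothelial-like cells, glucocorticoid-responsive genes were lower for 14 of 18 (-0.46, percentile 0.0).

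A few genes with a role in the circadian clock, picked after their values were seen and not a fixed list, had these values. Dbp was higher in zona glomerulosa-like cells (1.26, but -0.66 with other adrenal cells subtracted) and Ciart lower in PVN endothelial-like cells (-1.59). Per1 was lower in zona fasciculata-like cells (47.4 and 34.5 CPM, -0.46), and at 0.07 in neuron-like and -0.07 in corticotrope-like cells. The time of day at which each pool was collected is not given in the sources used here. Sex-linked check genes had medians of -0.03 in the whole PVN, -0.17 relative to the shift of all genes in the whole pituitary and -0.16 in the whole adrenal. Ddx3y, on the Y chromosome, was at 104 and 103 CPM in the PVN. Ly6k, lower in both cortex classes, came from few cells with high counts: in the control library 9 cells of cluster 1, 8 of cluster 3, 5 of cluster 6 and 6 of cluster 7 held it, and the richest cell of these clusters held 83 to 115 UMIs. In unnamed cortex cluster 2, 4 cells of each library held 58 and 111 UMIs, 82 of the latter in 1 cell (log2 ratio -0.10), and in cluster 4 it was 3 and 2 cells with 29 and 2 UMIs.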
